A study of Rattus norvegicus with 2 samples.

How the data were processed

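RNA was sequenced from H9c2 rat cardiomyoblasts held for 12 h in serum-free medium with 0.9 mM or 2.5 mM phosphate, 1 library per phosphate level. Per the file headers, the deposited values are FPKM (fragments mapped to a gene, relative to transcript length and to all mapped fragments), made by the authors and rounded to 2 decimals. The submitters' processing notes name bcl2fastq, TopHat2 2.1.1, Cufflinks 2.2.1, Cuffdiff and the rat genome build Rnor_6.0. Which step each tool served, the gene annotation, strand settings, the treatment of reads that match several places, and whether the libraries were scaled to each other are not given in the sources used here. FPKM from isoform-level estimation can be listed near 0 where an estimate fails, so values near 0 are given as listed.

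Each file held 8039 entries under numeric gene identifiers, identical between the files. Of these, 236 had no usable identifier (229 in scientific notation and 7 of more than 9 digits), and they were left out of the comparison. They were 2.94% of the entries and held 8.20% of the control and 8.56% of the high phosphate FPKM. Of the 7803 other identifiers, 7746 matched a symbol in an NCBI gene table for the assembly GRCr8, which was used only for names, transcript numbers and the order of neighbouring genes. The entries covered 40.6% of the protein-coding genes with a curated transcript in that table, so other genes were not analysed here. In each library 1113 entries were listed at 0, of which 481 were at 0 in both. Low values step by 0.01, the rounding of the files, so whole reads could not be recovered, the depth is unknown and no interval for counting error is given.

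The difference between the libraries was log2((high phosphate FPKM + 1)/(control FPKM + 1)), on FPKM as deposited, for the 4366 genes with a mean FPKM of at least 1 over both libraries. These genes are called measured. A gene counted as higher or lower from a 2-fold difference on this scale. With 1 library per phosphate level there was no test and no p-value. For each of 48 gene lists (pathways, checks of RNA quality and markers of other cell types) with at least 5 measured members, the median log2 ratio was given as a percentile among 10000 random lists of the same size, drawn within 20 bins of mean FPKM. A percentile of at most 2.5 or at least 97.5 was called outside the random lists.

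Named genes were chosen by a rule of size. They are the 12 highest and 12 lowest log2 ratios among genes with a symbol and a mean FPKM of at least 5, then up to 2 members at each end of every list described with any member at least 2-fold apart, the most abundant member of quality and cell type lists, and the phosphate carriers. Some genes that this rule selects are not reported here. The lists, the naming rule, the thresholds and 13 of the 15 alternative settings were chosen before the data were examined. The alternatives were other pseudocounts (0.1 and 0.5), 4 rescalings of the libraries, other filters on low values, other fold thresholds, lists without their largest or shared members and random lists not matched on expression.

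The calculations were tested on simulated libraries made from the 4366 genes, with a normal spread set from the median absolute deviation of the log2 ratios at each expression level and 200 genes changed by known folds. The folds were set on FPKM, whereas the rule works on FPKM + 1. A gene changed exactly 2-fold therefore lies under the threshold and passes only through the simulated spread. The 2-fold rule called 31.0% of genes changed 2-fold, 87.8% of those changed 3-fold, 92.7% of those changed 4-fold and 0.24% of 4166 unchanged genes. The observed log2 ratios have wider tails than this simulated spread, so the last value is not a rate of false calls in the data. Of 400 unchanged lists, 3.75% fell outside the random lists, and of 400 lists shifted by 0.5 log2 units 99.3% fell above them; these lists held independent genes. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.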

Results

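Gene expression was measured by RNA sequencing in H9c2 cells, a myoblast line derived from embryonic rat heart that is widely used as a cardiomyocyte precursor model. The cells were kept for 12 h in serum-free medium with 0.9 mM phosphate in the control and 2.5 mM phosphate in the treated culture. Each phosphate level had 1 library, so no difference reported here has a replicate check, and no test between conditions was possible. The files gave FPKM values for 8039 entries per library, with the same entries in both. Of these, 7803 had a usable gene identifier, and 4366 genes with a mean FPKM of at least 1 over the 2 libraries were compared. The number of reads behind each value is unknown, because the files hold FPKM and no counts. Listed FPKM values summed to 307622 in the control and 346857 in the high phosphate library. Across these genes the log-scale values of the libraries had a Pearson r of 0.980 and a Spearman rho of 0.979, which are correlations across genes, not across independent replicates.

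The comparison of high with control phosphate addressed how the transcriptome of cardiomyoblasts responds to raised extracellular phosphate, a question the series ties to cardiac remodelling. Among gene list medians in the main setting, genes that respond to low oxygen and genes of glycolysis stood highest in the high phosphate library. With a pseudocount of 0.1, fibrillar collagens and matrix stood level with glycolysis (both 0.83). Bnip3, a mitochondrial protein that promotes mitophagy, was listed at 51.3 FPKM in the control and 245 FPKM in high phosphate. Pdk1, the kinase that restrains pyruvate dehydrogenase, was listed at 7.84 and 42.5 FPKM, and the glucose transporter Slc2a1 at 60.2 and 167 FPKM. The lists of fibrillar collagens and matrix, cholesterol synthesis, G2 and mitosis, the interferon response and the unfolded protein response were also higher as groups. Heat shock genes were modestly lower as a group. Id3 and Smad7 were at least 2-fold lower, while the list of TGF-beta and BMP targets to which both belong lay inside the random lists, with 5 of its 11 measured members higher and 6 lower.

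By the rule of at least 2-fold on the scale of log2(FPKM + 1), 77 genes were higher and 38 were lower in the high phosphate library, together 2.63% of the genes compared. Because of the added 1, this scale understates the difference of genes with low values. All 2-fold counts and calls given here are on this scale. Some genes not counted therefore had listed FPKM more than 2-fold apart. Most of the lower genes had low values: among genes with a mean of at least 10 FPKM, 27 were higher and 3 lower, whereas below a mean of 5 FPKM 36 were higher and 30 lower. The size of this imbalance depended on the scaling. After both libraries were rescaled to the same sum, 57 genes were higher and 57 lower. The counts were 73 and 38 at the same median ratio and 71 and 40 at the same upper quartile. They were 66 and 45 for the sum without the 100 most abundant genes. Each sum was taken over the 8039 listed entries, not over all genes, and abundant genes weigh most in it. Under the rescaling to the same sum the median log2 ratio of all genes moved from 0.00 to -0.15. The central 95% of log2 ratios ran from -0.65 to 0.88 over all genes, from -1.02 to 1.18 in the lowest of 5 equal bins of mean FPKM and from -0.42 to 0.79 in the highest bin.

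**Figure D1:**
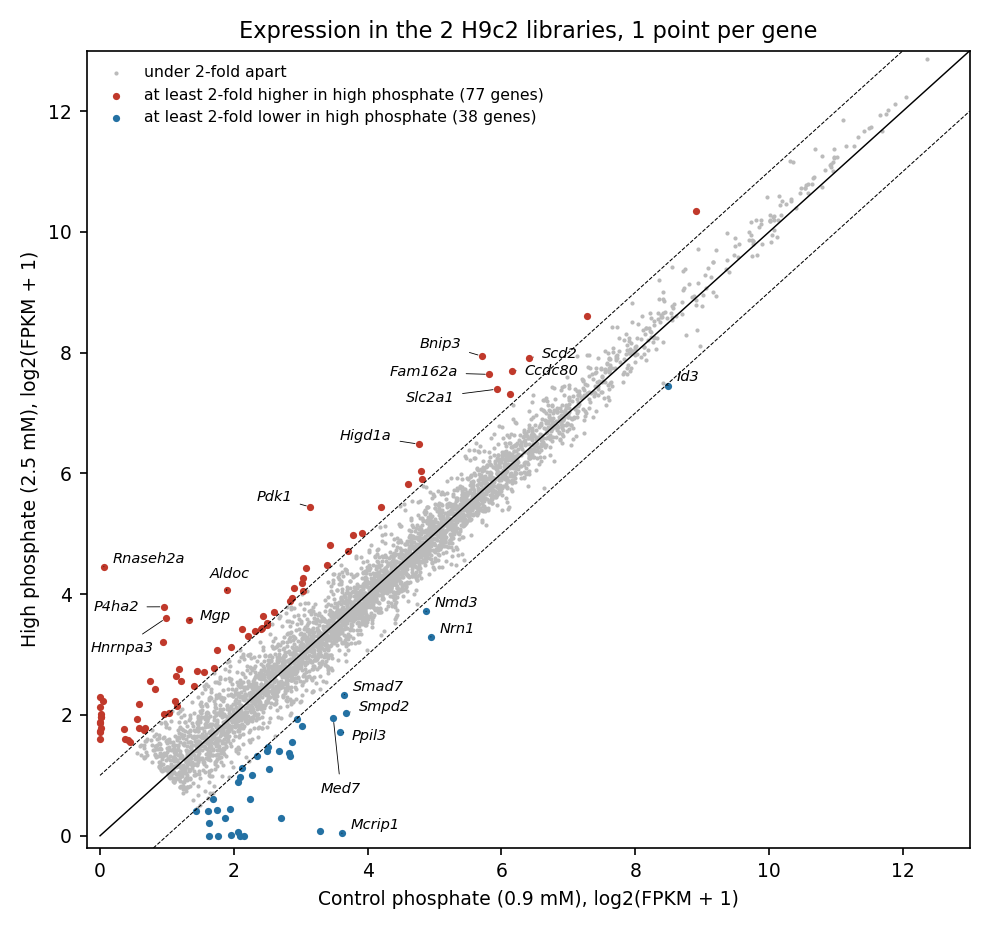
Each point is 1 of the 4366 genes compared, with log2(FPKM + 1) in the control phosphate library on the horizontal axis and in the high phosphate library on the vertical axis; the solid line marks equal values and the dashed lines 2-fold differences. The 77 genes at least 2-fold higher in high phosphate are red and the 38 lower ones blue. This split became 57 and 57 after rescaling to the same sum of the listed entries, and 73 and 38 at the same median ratio.

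The 12 highest log2 ratios among named genes with a mean of at least 5 FPKM were led by Rnaseh2a, the catalytic subunit of RNase H2, listed at 0.04 FPKM in the control and 20.9 FPKM in high phosphate. P4ha2, a collagen prolyl hydroxylase subunit, was listed at 0.94 and 12.9 FPKM, and Hnrnpa3, an RNA-binding protein, at 0.98 and 11.2 FPKM. Mgp, the matrix Gla protein that inhibits calcification of soft tissue, was listed at 1.52 and 10.9 FPKM (log2 ratio 2.24). Higher at larger values were Fam162a with 55.5 and 199 FPKM, the mitochondrial inner membrane protein gene Higd1a with 26.3 and 88.5 FPKM, the secreted matrix protein gene Ccdc80 with 70.4 and 207 FPKM, and the stearoyl-CoA desaturase Scd2 with 84.5 and 241 FPKM. Bnip3 (Entrez 84480), Pdk1 (116551), Aldoc (24191) and Slc2a1 (24778) completed the 12, with log2 ratios of 2.23, 2.30, 2.17 and 1.46.

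At the other end, Mcrip1 was listed at 11.3 FPKM in the control and 0.03 FPKM in high phosphate. Ppil3, a cyclophilin family member, was listed at 11.0 and 2.29 FPKM. Nrn1, a membrane-anchored promoter of neurite outgrowth, was listed at 29.8 and 8.8 FPKM. Smpd2, a neutral sphingomyelinase, had 11.8 and 3.11 FPKM, and the Mediator subunit Med7 10.2 and 2.85 FPKM. Smad7, the inhibitory SMAD, had 11.6 and 4.05 FPKM (log2 ratio -1.32), the ribosome export adaptor Nmd3 28.3 and 12.2 FPKM, and the inhibitor of differentiation Id3 358 and 175 FPKM (log2 ratio -1.03). Abce1, the quinone reductase Nqo1 and Lyset were also among the 12 lowest but under 2-fold, with log2 ratios of -0.91, -0.91 and -0.89. Each of these 3 passed 2-fold after rescaling to the same sum. Rnaseh2a, P4ha2, Hnrnpa3 and Mcrip1 were each under 1 FPKM in 1 library, where a value near 0 can also be a failed estimate. Hnrnpa3, like Gapdh and many ribosomal protein genes, has near-identical copies in the genome, and how shared reads were assigned is not given in the sources used here.

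Of 48 gene lists fixed before the data were examined, 36 had at least 5 measured members. For each, the median log2 ratio was placed among 10000 random lists of the same size matched on mean expression, which describes these 2 libraries and not the effect of phosphate. Medians of 12 lists lay above the central 95% of the random lists, 2 lay below and 22 inside, where 1.8 of 36 would fall outside by chance if genes varied independently. Genes of 1 pathway vary together between any pair of cultures, so more than 1.8 lists can fall outside without an effect of phosphate. Counts of higher and lower members refer to FPKM as deposited. After rescaling to the same sum, which shifts the log2 ratios of all genes down, the number higher was 10 of 12 for glycolysis, 26 of 32 for G2 and mitosis, 10 of 13 for the unfolded protein response and 8 of 11 for the contractile genes, and the number lower was 11 of 13 for heat shock genes and 27 of 29 for S phase genes.

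All 11 measured members of the list of hypoxia and HIF1 targets were higher in the high phosphate library, with a median log2 ratio of 1.37 at percentile 100. At least 2-fold higher were 7 of them. Besides P4ha2, Pdk1, Bnip3, Higd1a and Slc2a1, these were Ddit4, an inhibitor of mTORC1 signalling, with 9.83 and 27.1 FPKM, and the MYC antagonist Mxi1 with 3.63 and 8.91 FPKM. On the scale with the added 1, Mxi1 was under 2-fold after rescaling to the same sum (log2 ratio 0.95). The smallest differences were those of Vegfa, the angiogenic growth factor, with 7.59 and 9.77 FPKM, and P4ha1 with 13.2 and 23.9 FPKM. Of the measured members, only Adm and Higd1a are in no other list. The others are shared with the glycolysis, matrix, FOXO, ATF4, apoptosis or growth factor lists, so the list could not be computed without shared members.

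In the glycolysis list, 11 of 12 measured members were higher and 5 were at least 2-fold higher, with a median log2 ratio of 0.83 at percentile 100. The 5 were Pdk1 and Slc2a1, which are also in the hypoxia list, Aldoc with 2.71 and 15.7 FPKM, phosphoglycerate kinase Pgk1 with 481 and 1307 FPKM, and glucose-6-phosphate isomerase Gpi with 154 and 389 FPKM. Pdk2 was listed at 13.9 and 13.5 FPKM and the muscle isoform Pgam2 at 1.06 and 1.07 FPKM. The most abundant enzymes of the list were chosen for mention after their values were seen: Gapdh with 2197 and 3710 FPKM, Aldoa with 1315 and 2287 FPKM and Ldha with 1269 and 2311 FPKM. The tricarboxylic acid cycle list (percentile 15.1) and the nuclear genes of oxidative phosphorylation (percentile 53.1) lay inside the random lists.

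All 15 measured members of the list of fibrillar collagens and matrix genes were higher as deposited and 14 after rescaling to the same sum. Their median log2 ratio as deposited was 0.79 at percentile 100. With the added 1, 1 of them, P4ha2, was at least 2-fold higher. Plod2 and Col1a1 were more than 2-fold apart only in listed FPKM. This list shares P4ha1, P4ha2 and Plod2 with the hypoxia list. Plod2, a lysyl hydroxylase of collagen, had 4.72 and 10.1 FPKM, while the thrombospondin Thbs1, the member whose sign turned (log2 ratio 0.17, and -0.01 rescaled), had 833 and 934 FPKM and the collagen chaperone Serpinh1 1426 and 1693 FPKM. Collagen genes were named after their values were seen: Col3a1 was listed at 489 and 844 FPKM, Col4a1 at 87.4 and 156 FPKM and Col1a1 at 0.79 and 1.8 FPKM. No other collagen of the list was measured, Col4a1 is not a fibrillar collagen and Col1a1 was low in both libraries. Of the 40 genes written for the list, 19 were listed in these data, so it gives no broad view of fibrillar collagens. Fibroblast markers, 4 of whose 8 measured members are in the matrix list, had a median log2 ratio of 0.55 at percentile 99.95, and their most abundant member, S100a4, had 3291 and 3249 FPKM. The fibroblast list fell inside the random lists without the filter on low values (percentile 91.9) and among genes of at least 10 FPKM (percentile 95.9).

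All 14 measured members of the cholesterol synthesis and SREBP2 list were higher, with a median log2 ratio of 0.76 at percentile 100. Hmgcs1, the synthase that makes HMG-CoA, was listed at 2.87 and 7.77 FPKM, and squalene epoxidase Sqle at 27.1 and 59.3 FPKM. Lss and Mvk, with log2 ratios of 0.26 and 0.28, differed least. Fatty acid synthesis and SREBP1 targets lay inside the random lists (percentile 86.0), with members on both sides: besides Scd2, Scd had 4.62 and 10.6 FPKM, whereas fatty acid synthase Fasn had 23.1 and 17.4 FPKM and Mid1ip1 16.0 and 13.9 FPKM. Without the filter on low values, the SREBP1 list lay above the random lists (percentile 99.8). On the scale with the added 1, Sqle and Scd were under 2-fold after rescaling to the same sum (log2 ratios 0.93 and 0.89).

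**Figure D2:**
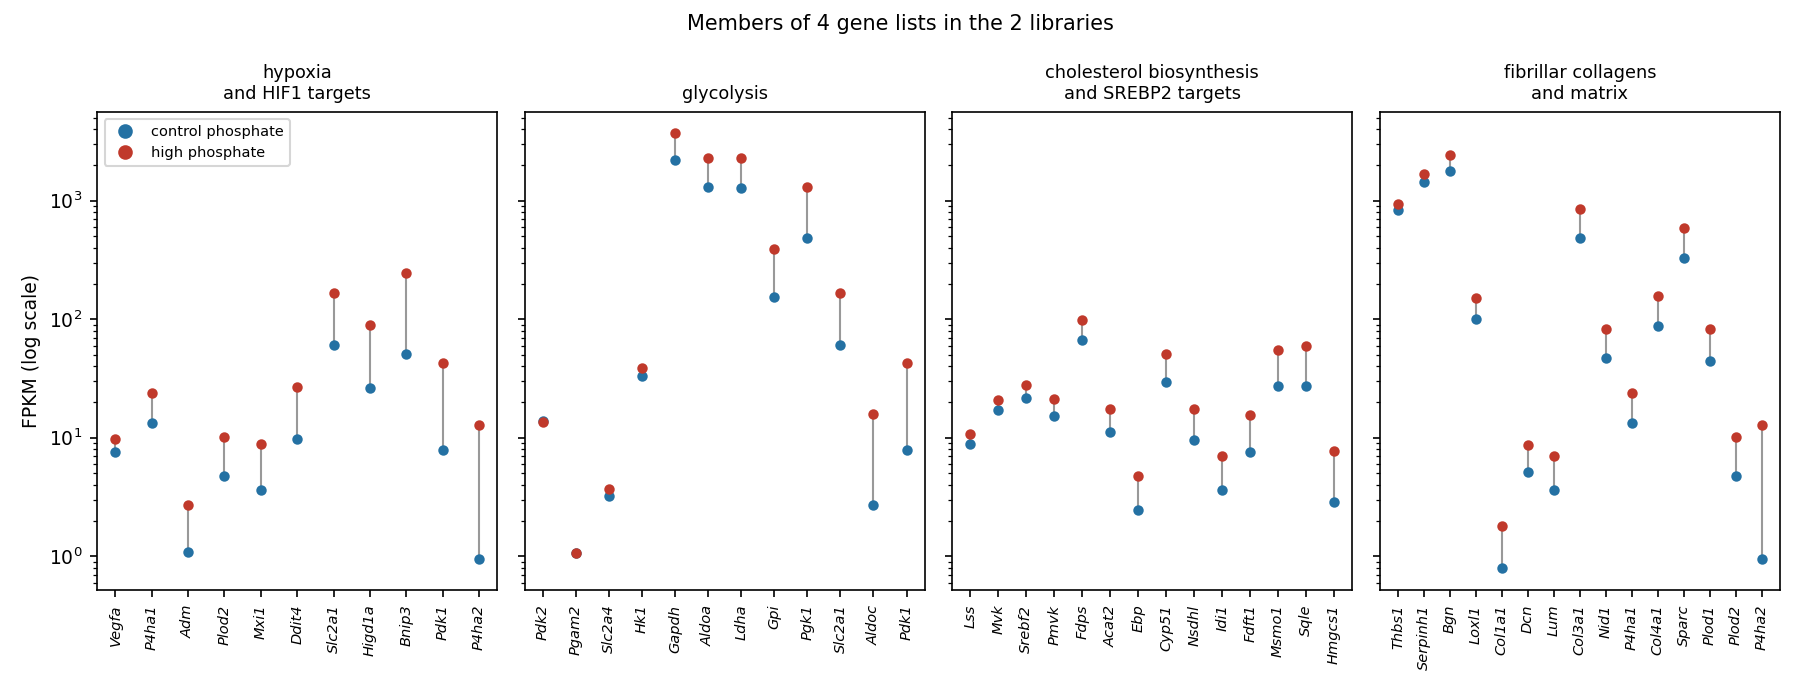
Points give FPKM on a logarithmic axis for each measured member of 4 gene lists in the control phosphate library (blue) and the high phosphate library (red), with a line joining the values of 1 gene. All 11 hypoxia, 14 cholesterol and 15 matrix genes and 11 of the 12 glycolysis genes are higher in the high phosphate library as deposited; after rescaling to the same sum this held for 11, 14, 14 and 10 genes.

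Among cell cycle genes, 30 of 32 members of the G2 and mitosis list were higher, with a median log2 ratio of 0.54 at percentile 100. Securin, encoded by Pttg1, was listed at 0.33 and 2.01 FPKM and was the 1 member at least 2-fold higher with the added 1. The spindle assembly factor Tpx2 had 4.93 and 10.4 FPKM, more than 2-fold apart only without the added 1. Aurkb had 7.57 and 5.17 FPKM and Foxm1 3.5 and 2.97 FPKM. By contrast, 22 of 29 genes of S phase and DNA replication were lower, with a median log2 ratio of -0.12 at percentile 2.98, just inside the random lists and outside them after rescaling to the same sum (percentile 2.18). Its lowest members were the helicase subunit Mcm4 with 3.11 and 1.64 FPKM and the licensing factor Cdt1 with 17.2 and 12.1 FPKM, and its highest Rpa3 with a log2 ratio of 0.37. The list of cyclins, CDKs and inhibitors lay above (median 0.30, percentile 98.9), with the inhibitors Cdkn1a at 1.73 and 5.6 FPKM and Cdkn1b at 15.5 and 27.1 FPKM highest, and Cdk2 and Ccne1 lowest with log2 ratios of -0.56 and -0.37. That position was lost without its largest member (percentile 82.0), and its median was -0.01 among genes of at least 5 FPKM.

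Of 22 measured interferon response genes, 17 were higher, with a median log2 ratio of 0.47 at percentile 100. With the added 1 none reached 2-fold, although the listed FPKM of Ifit2 were slightly more than 2-fold apart. Ifit1 and Ifit2, antiviral RNA-binding proteins, were listed at 22.2 and 44.1 FPKM and at 2.37 and 4.85 FPKM, while the transcription factor Irf1 had a log2 ratio of -0.17. In the unfolded protein response list, 11 of 13 members were higher, with a median log2 ratio of 0.42 at percentile 99.97. The chaperone Hsp90b1 had 374 and 685 FPKM and the disulfide isomerase Pdia6 245 and 450 FPKM, and Selenos and Syvn1 had log2 ratios of -0.01 and -0.03. Amino acid response genes downstream of ATF4 lay inside the random lists (percentile 41.9). The NF-kB and cytokine list had a median log2 ratio of -0.16 at percentile 2.24, but its mean was 0.05. Cxcl1 was listed at 98.1 and 52.9 FPKM and the inhibitor Nfkbia at 34.9 and 22.3 FPKM, against Cxcl12 with 1.93 and 4.61 FPKM and Ccl5 with 5.91 and 10.8 FPKM. Without the filter on low values, the NF-kB list lay above the random lists (percentile 99.5).

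In the heat shock list, 10 of 13 members were lower, with a median log2 ratio of -0.19 at percentile 0.195. The HSP90 cochaperone Ahsa1 had 149 and 100.4 FPKM and the heat shock factor Hsf1 15.1 and 11.0 FPKM, whereas the mitochondrial chaperonin Hspd1 had 6.63 and 9.6 FPKM and Dnajb4 20.8 and 28.2 FPKM. Of 9 FOXO targets and growth factor withdrawal genes, 6 were higher, with a median log2 ratio of 0.49 at percentile 99.9. Its highest members were Mxi1 and the receptor Igf1r, listed at 0.96 and 2.67 FPKM, and its lowest Irs2 and Foxo4 with log2 ratios of -0.33 and -0.15. Smooth muscle and SRF contractile genes were higher in 10 of 11 cases (median 0.34, percentile 99.6), with smooth muscle actin Acta2 at 1647 and 2651 FPKM and calponin Cnn1 at 28.1 and 40.8 FPKM highest, and Myl9 and Tpm1 lowest with log2 ratios of 0.05 and -0.24. Of 20 fatty acid oxidation genes 15 were higher as deposited and 11 after rescaling to the same sum (median 0.18 at percentile 98.5, and 0.01 rescaled, 0.16 above the median of all genes), and its lowest members were Cpt1a, which admits fatty acids to mitochondria, with 20.5 and 11.3 FPKM, and the fatty acid binding protein Fabp3 with 485 and 330 FPKM. The same list was inside the random lists among genes of at least 10 FPKM (percentile 95.1).

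**Figure D3:**
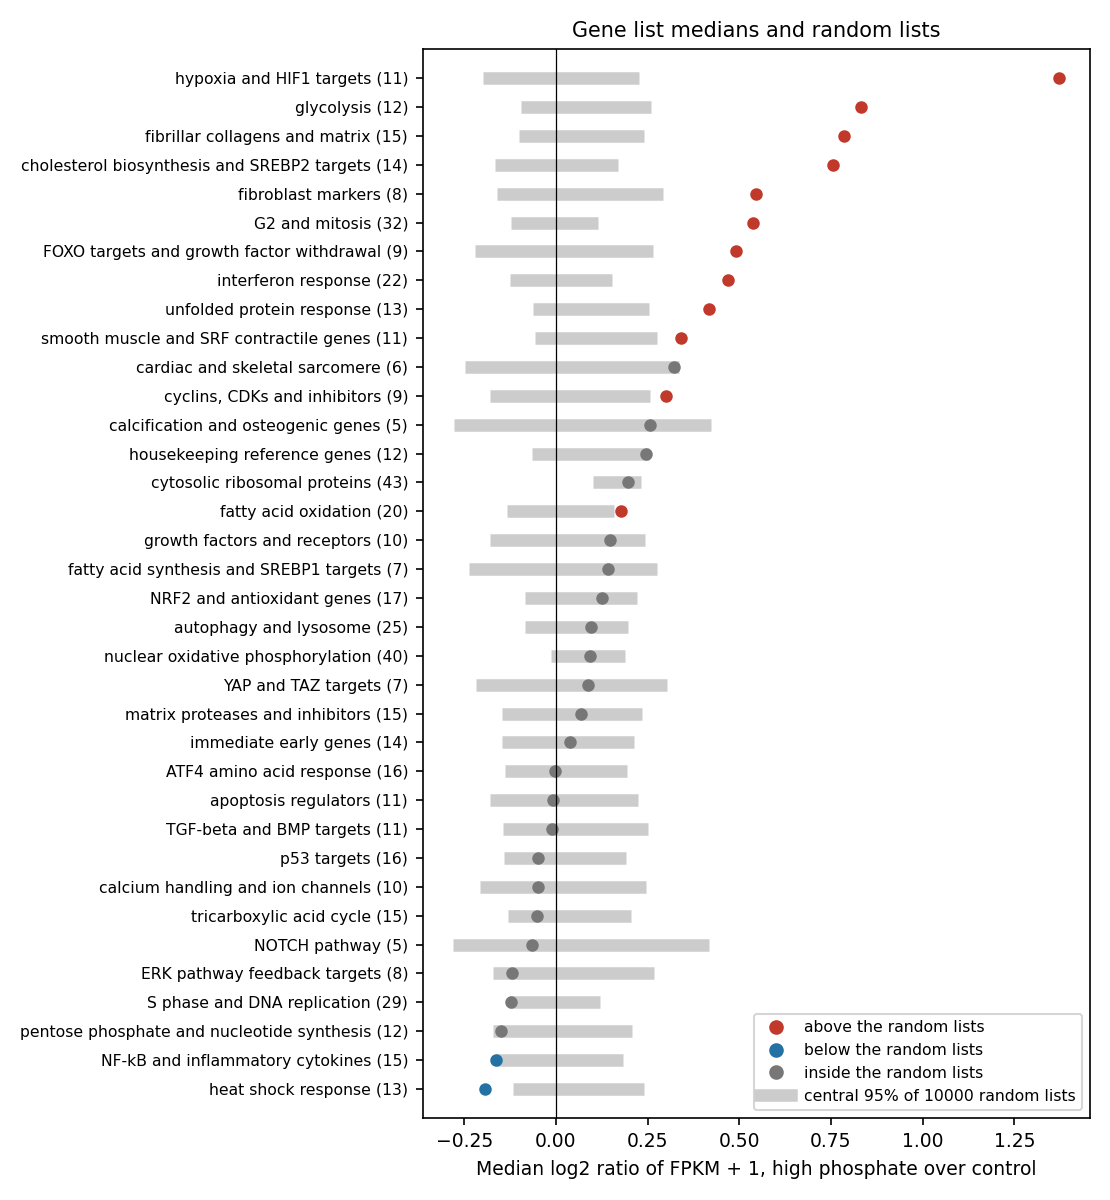
Points give the median log2 ratio of FPKM + 1, high phosphate over control, for the 36 gene lists with at least 5 measured members (number in brackets), and grey bars the central 95% of 10000 random lists matched on expression. Red points (12 lists) lie above and blue points (2 lists) below the bars, with hypoxia and HIF1 targets at 1.37 and heat shock genes at -0.19 at the ends. The medians of the NF-kB and cyclin lists changed sign under other filters on low values.

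Few genes closest to phosphate handling and heart muscle could be compared. Listed were 9 of 26 phosphate transport and mineral genes, 9 of 25 hypertrophy and fetal cardiac genes and 20 of 38 sarcomere genes. Of these listed genes 4, 4 and 6 had a mean of at least 1 FPKM, and the others were lower. The phosphate carriers Slc20a1, Slc20a2 and Xpr1 were not analysed here. Of the phosphate transport and mineral list, 4 genes were measured: the pyrophosphate transport protein Ankh with 0.58 and 1.47 FPKM, Nherf1 with 26.1 and 28.8 FPKM, Pdzk1 with 1.11 and 1.07 FPKM and Fgfr3 with 2.29 and 1.27 FPKM. Calcification and osteogenic genes (percentile 89.7) held the 2.24 of Mgp beside osteopontin, Spp1, at 1985 and 2058 FPKM and Msx1 at 2.4 and 1.8 FPKM. Of the hypertrophy and fetal cardiac genes 4 were measured, with log2 ratios of 0.56 for the calcineurin regulator Rcan1, 0.21 for Nfatc4, 0.04 for Acta1 and -0.04 for Atp2a2. The sarcomere list lay inside the random lists (percentile 97.0), with Casq2 at 47.6 and 75.5 FPKM. The myogenic factor Myod1 was listed at 6.11 and 1.59 FPKM, the 1 gene at least 2-fold apart among 4 measured myogenic regulators.

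The remaining lists lay inside the random lists. Percentiles were 58.7 for immediate early genes, 7.38 for ERK feedback targets, 29.1 for TGF-beta and BMP targets, 72.9 for YAP and TAZ targets, 30.4 for the NOTCH pathway, 61.4 for matrix proteases and inhibitors and 4.39 for pentose phosphate and nucleotide synthesis, where 11 of 12 members were lower. They were 72.1 for NRF2 and antioxidant genes, 23.2 for p53 targets, 44.9 for apoptosis regulators, 70.6 for autophagy and lysosome genes, 35.7 for calcium handling and ion channels and 87.3 for growth factors and receptors. Matrix proteases lay above the random lists without members shared with another list (percentile 99.4). From a mean of 5 FPKM their median turned to -0.07. No direction is given for lists whose median turned from above to below 0 with the shift of all genes by rescaling to the same sum, 8 of those inside the random lists, oxidative phosphorylation and autophagy among them. All 8 stayed above the median of all genes, by 0.02 to 0.14. Further genes at least 2-fold apart in lists inside the random lists were Id3 and Smad7 in the TGF-beta list, Gpx4, which detoxifies lipid peroxides, with 4.78 and 1.16 FPKM, the growth factor Fgf7 with 2.09 and 0.16 FPKM, the protease inhibitor Serpine2 with 4.63 and 10.3 FPKM and the dehydrogenase Idh1 with 0.49 and 2.45 FPKM. On the scale with the added 1, Serpine2 was under 2-fold after each of the 4 rescalings.

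Among lists kept as checks of the RNA, cytosolic ribosomal proteins lay inside the random lists (43 members, median 0.20, percentile 71.8), with Rps29 the most abundant at 3770 and 4464 FPKM. Housekeeping genes also lay inside them (12 members, median 0.25, percentile 96.5), with Eef1a1 the most abundant at 3496 and 4164 FPKM. Genes used as references were not level between the libraries, since Pgk1 and Gapdh are in that list too. Lists of endothelial, epithelial, leukocyte, adipocyte, neural and erythroid markers had at most 2 measured members each. The endothelial list had 1 measured member, Eng, with 39.1 and 26.6 FPKM. The epithelial list had 2, led by Krt8 with 140 and 247 FPKM. The leukocyte and adipocyte lists had 2 each, led by Lcp1 with 6.88 and 6.76 FPKM and Cebpa with 9.51 and 8.8 FPKM. The neural and erythroid lists had 0 measured members, since their 6 and 3 listed genes all had a mean under 1 FPKM. The other listed genes of the endothelial, epithelial, leukocyte and adipocyte lists were also under that mean. Mitochondrially encoded genes were not analysed here. Replication-dependent histones had 3 measured members and WNT targets 4, with Fzd2 at 24.4 and 45.4 FPKM and Ccn5 at 68.2 and 42.6 FPKM at the ends of the latter.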

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

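The counts in this part were chosen after the data were seen. They concern entries that the comparison did not use, those without a usable gene identifier. Of 89 such entries with a mean FPKM of at least 1, 5 were at least 2-fold higher in the high phosphate library and 0 were at least 2-fold lower, with a median log2 ratio of 0.12. Those 5 were 5.62% of the entries, against 1.76% of the genes compared that were at least 2-fold higher. The highest was listed at 0 FPKM in the control and 3.78 FPKM in high phosphate, where the 0 can be a failed estimate, and 4 of the 5 were above 1 FPKM in the control. The genes behind these entries are not known here.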

How the results depend on the processing

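Settings in this part were planned except the inclusion of entries without a usable identifier and the limit of 10 FPKM, both chosen after the data were seen. Of the 14 lists outside the random lists, 10 stayed on their side in every alternative run for them, as did 16 of 22 inside. Some lists fell under 5 members in some alternatives and were not computed there. Among these was the hypoxia list without members shared with another list, so its position was not checked in that way. Counts of higher and lower genes were 151 and 62 with a pseudocount of 0.1, 41 and 8 from a mean of 5 FPKM, 315 and 147 at 1.5-fold, 25 and 13 at 3-fold, and 57 and 57 after rescaling to the same sum. Fewer genes entered at 5 FPKM; for the pseudocount the added value itself sets how low genes are weighed. The central 95% of log2 ratios spanned 1.53, and 1.99, 1.72 and 1.36 with pseudocounts of 0.1 and 0.5 and from 5 FPKM. The share of genes above 0 was 50.5%, and 32.2% after rescaling to the same sum, 47.6% at the same upper quartile and 40.7% for the sum without the 100 most abundant genes. The NF-kB percentile was 2.87 and 2.53 with pseudocounts of 0.1 and 0.5, 2.63 from 5 FPKM, 2.74 without shared members and, on the other side, 99.5 without a filter. Cyclins lay at 52.3 without a filter, 82.0 without the largest member and, with a median below 0, at 42.9 from 5 FPKM, 37.9 from 10 FPKM and 39.2 without shared members. S phase genes lay at 2.18 after the sum rescaling, 2.50 at the same upper quartile and 2.15 against unmatched random lists. Without a filter, SREBP1 targets lay at 99.8, housekeeping genes at 97.53 and fibroblast markers at 91.9. Against unmatched lists, housekeeping genes lay at 98.5, sarcomere genes at 97.8 and ribosomal proteins at 99.9. Matrix proteases lay at 99.4 without shared members. From 10 FPKM, fatty acid oxidation lay at 95.1 and fibroblast markers at 95.9. Where no cause is given, the cause was not tested. Of 160 named genes followed, 34 were at least 2-fold apart, and 30 of these stayed so under every pseudocount and rescaling. Their direction could not change, because a pseudocount cannot turn a sign and the rescaling to the same sum shifts log2 ratios by at most 0.17. Changes of sign among genes under 2-fold, such as that of Thbs1, were not counted. Summing repeated symbols, adding genes of 1 file, confidence bounds and leaving out a replicate could not be run, because no symbol repeated, both files list the same entries, no bounds are given and each level had 1 library. No depth is known, so what depth limits could not be measured.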

Other observations

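The grouping of genes by symbol and the tests of the abundance trend in the hypoxia list, of unstable low values, of oxygen or cell density, of 1 scaling factor and of transcript numbers were chosen after the results were seen. Gene families grouped by the letters of their symbols gave 55 families with at least 8 measured members, of which 5 lay above and 4 below the random lists, where 2.75 would fall outside by chance if genes varied independently. The families share no tested theme. Of 55 genes of mitochondrial ribosomal proteins (symbols Mrpl and Mrps), 14 were above 0, with a median log2 ratio of -0.14 at percentile 0.04. Genes with symbols in Pol, subunits of RNA and DNA polymerases, had a median of -0.19 over 24 genes at percentile 0.21, proteasome genes (Psm) -0.09 over 34 genes at percentile 0.67, and translation initiation factors (Eif) -0.11 over 33 genes at percentile 0.775. Above the random lists were the interferon-induced Ifi genes (median 0.51 over 8 genes, percentile 99.95), the kinesins in Kif (0.40 over 10 genes, 99.8), the glutathione transferases in Gst (0.41 over 9 genes, 99.8), Fam (0.16 over 32 genes, 99.0) and Nud (0.24 over 10 genes, 97.56). The 8 Ifi genes include Ifit1, Ifit2, Ifit3, Ifi27 and Ifi44 of the interferon list. The 10 Kif genes include Kif4a, Kif11, Kif20a and Kif22 of the mitosis list. Gst shares Gstm1, Gstp1, Gsta1 and Gsta4 with the NRF2 list. Pol shares Pola1, Pola2 and Pole2 with the S phase list and Polr2a with the housekeeping list. Psm shares Psmb8 and Psmb9 with the interferon list, and Fam shares Fam83d with the mitosis list. These families are therefore not separate from the list results. After rescaling to the same sum the Fam median was near 0, 0.15 above the median of all genes. Cytosolic ribosomal proteins, in contrast, were inside the random lists, and 2 of their 43 members were listed under 10 FPKM in the control, where the list's median was 1279 FPKM: Rps24 at 5.91 and 3.67 FPKM and Rpl28 at 1.81 and 1.79 FPKM.

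The higher hypoxia and HIF1 target list was weighed against technical explanations. An abundance trend between the libraries is argued against by the list's percentile of 100 among random lists matched on expression, and unstable low values by a median log2 ratio of 1.59 over the 6 members with a mean of at least 10 FPKM. Another set was written with 50 HIF targets and used without any gene of the lists fixed before. It had 11 measured genes, 9 of them higher, with a median log2 ratio of 0.62 at percentile 100. Gbe1, Insig2 and Zfp395 were at least 2-fold higher, whereas Cited2 and Rab20 were lower, with log2 ratios of -0.37 and -0.06. Higher HIF activity in the high phosphate culture is therefore a hypothesis that these data allow. Whether it may come from phosphate or from oxygen or cell density that differed between the dishes for another reason cannot be told apart, because there was 1 library per phosphate level.

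The most abundant genes were higher in the high phosphate library: the median log2 ratio of the top 5% of genes exceeded that of the rest by 0.198 (95% bootstrap interval over genes 0.174 to 0.218, 218 against 4148 genes). A difference of 1 scaling factor moves both sets nearly alike on this scale. On log2 ratios without the added 1 it moves them exactly alike, so it adds nothing to the difference there. That difference was 0.201 (0.175 to 0.222), which argues against 1 scaling factor as its cause. Ribosomal protein genes, 41 of the 218, did not account for the difference on the scale with the added 1. Without them it was 0.179 (0.133 to 0.224, 177 against 4141 genes). A difference in how the libraries were made and a difference in the cells remain open, and no biological explanation was tested.

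Rnaseh2a, P4ha2, Hnrnpa3 and Mcrip1 were at least 10 times apart with a mean of at least 5 FPKM, each under 1 FPKM in 1 library. A failed assignment of reads among annotated transcripts might produce such values: the 4 genes had a median of 8 RefSeq transcripts, at percentile 98.1 among genes matched on expression, but 4 genes are too few to decide and the annotation the authors used is not given in the sources used here. Assignment of reads to the adjacent gene was not seen, with 0 of the 4 having a neighbour at least 2-fold apart in the other direction. Both neighbours were in the files for 1 of the 4, so that explanation cannot be told apart either.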
